A study of Mus musculus with 8 samples.

How the data were processed

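RNA was measured in 8 libraries of cultured mouse bone marrow-derived MDSCs, 4 untreated and 4 treated with Romidepsin. The deposited values are raw counts, whole-number read counts per Ensembl gene for every library. Per the labels' protocols, poly(A) RNA was selected with a NEBNext module and the libraries were sequenced on an Illumina NextSeq 500. Per the submitters' processing notes, FastQC, STAR 2.5.2a and DESeq2 were used with the GRCm38 (mm10) genome. The counting tool, the annotation release, the strand setting and any filter on the counts are not given in the sources used here. Reads of overlapping and antisense genes, and of near-identical copies, may therefore be assigned to either gene, and values of such genes are uncertain. Of 108 genes named in the results, Cd74, H1fx, Irf9, Pfkm and Rps10 share exon sequence with another annotated gene on the same strand, and Bak1, Bhlhe40, Ccnd1, Cd22, Cd274, Cdkn1a, Ciita, Dhx58, Gadd45a, Gfi1, H1f0, H1fx, Hdac7, Hspa1a, Il1a, Il1b, Mt2, Ncf1, Pfkm, Psmb8, Psmb9, Rps10, Syn1 and Uchl1 with one on the opposite strand. Genes named only for the processing settings can overlap others as well. Among them are Hdac5 on the same strand and Aldoa, Cebpb and H2afy on the opposite strand. Of 26930 gene identifiers in the table, 26881 matched a gene symbol in the reference table and 49 did not. No gene had a count of 0 in all libraries, no library was a copy of another, and every row named a gene. Coordinates are those of the GENCODE annotation on GRCm38.

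Groups were taken from the sample titles. Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr (12852 genes), library composition was adjusted by the trimmed mean of M-values (TMM), and treated and untreated libraries were compared by the two-sided quasi-likelihood F test with robust dispersion estimates. Adjusted p-values throughout are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and log2 fold changes are treated over untreated. A 2-fold difference refers to the estimated fold change, not to a test against that size. CPM values are TMM-scaled. Total counts per library ranged from 12996892 to 23176949, so that a gene at 1 CPM rests on few counts and its fold change is imprecise.

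The test design, the alternatives, 29 gene lists and the rule for the genes to name were written before the data were examined. The rule took the 10 highest and 10 lowest fold changes among called genes with a mean of at least 10 CPM and no overlap between groups, leaving out predicted genes, pseudogenes and unnamed identifiers. In each list it took up to 3 called members with the smallest p in the majority direction, up to 1 in the other direction, and at most 1 uncalled member, the most highly expressed. It always took 16 genes, which were Hdac1, Hdac2, Hdac3, Cdkn1a, Cdkn2a, Apoe, Trem2, Arg1, Nos2, S100a8, S100a9, Cd274, Il1b, Il6, Bcl2l1 and Mcl1. The text names a part of the genes the rule took, 1 of the 10 highest is not reported here, and genes named outside the rule were chosen after their values were seen. The lists cover HDACs, histones, CDK inhibitors, p53 targets, secretory phenotype, lipid handling, suppressor effectors, neutrophil, monocyte and dendritic cell genes, interferon-stimulated genes, cell death, cell cycle, recombination, NF-kB, chemoattractant receptors, neuronal genes, transcription factors, stress, metabolism, housekeeping and mitochondrial genes, and markers of 5 other cell classes. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and limma's fry, which tests whether a list moves on balance in one direction and not whether it differs from other genes, were alternatives.

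The groups share replicate numbers, and whether these pair the samples was checked on the deviations of each library from its group mean. Libraries with the same number correlated at 0.525, 0.270, 0.457 and 0.171 for numbers 1 to 4, and each library correlated best with its own number, the highest value between numbers being 0.0467. Every pair lies above 0.1, the bound set for pairing, so the numbers were taken to pair the samples. The pairing comes from the data, since no label says what a number marks. The reported fit was fixed before this check and leaves the pairing out. Genes said not to pass failed in that unpaired fit, and some of them passed with the block. The fit with a replicate block is given beside a result where it changes the call or moves a count by more than 1.5 times, as are counts of list members without treated replicate 3, without both libraries of number 3, and with library size or housekeeping scaling.

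Other alternatives were DESeq2 size factors, library size alone, upper-quartile scaling, scaling to the summed counts of 20 housekeeping genes, no count filter, a minimum mean of 10 CPM, the DESeq2 1.42.0 Wald test, limma-voom and leaving out each library in turn. Added after seeing the data were fits without both libraries of number 3, camera with an estimated correlation and the replicate block, and the counts of list members in fits other than the reported one. The tests were run on simulated counts drawn from the means, depths and dispersions of these libraries, with 200 genes changed. For the 4 against 4 comparison over 12852 genes, edgeR recovered 96% of genes changed 8-fold, 70% of those changed 4-fold, 4% of those changed 2-fold and 2% of those changed 1.5-fold, with 2 false calls (2.27%). With the replicate block it recovered 90%, 60%, 2% and 0%, limma-voom 94%, 68%, 2% and 2%, and DESeq2 98%, 86%, 32% and 4%, with 3.80%, 1.19% and 22.5% false calls. The simulated counts hold no effect of the replicate number, so they cannot show what the block gains in paired samples. With only 200 genes changed, the shares of false calls do not carry over to data with 4690 calls. Simulated data without any change gave 0 called genes in edgeR and 0 lists called by camera. A list of interferon-stimulated genes lowered 2-fold was called by camera with either correlation and by fry. The simulated genes were drawn independently, whereas the estimated correlation within this list in the data was 0.898. These simulations therefore do not show how the list tests behave with correlated genes. The statistics of the closing section were simulated after their first results were seen: the implied treated share of known mixtures of 0.4 and 0.7 came out at 0.362 and 0.609 from rising and 0.456 and 0.739 from falling genes, 5.5% of 200 sets of 8 equal markers gave a permutation p under 0.05, and baseline and fold change from different libraries without any change had a rank correlation of −0.00935. Bootstrap intervals used 2000 samples and permutation tests 100000.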

Results

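Gene expression was measured by RNA sequencing of poly(A) RNA from mouse myeloid-derived suppressor cells (MDSCs), immature myeloid cells that restrain T cells. The cells were grown from C57BL/6 bone marrow with GM-CSF and IL-6, both at 40 ng/ml, and were given medium conditioned by TRAMP-C1 mouse prostate tumour cells on day 4. The labels call the resulting cells senescent-like. The 8 libraries form 2 groups of 4: untreated cells, and cells given the histone deacetylase (HDAC) inhibitor Romidepsin at 0.5 µM for 6 h. Total counts per library ranged from 12996892 to 23176949, with untreated replicate 4 the deepest and the next deepest, treated replicate 3, at 15396077. The comparison asks how Romidepsin changes the transcriptome of these cells. The labels name no separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Fold changes are log2 values of treated over untreated cells with their standard error (SE), and expression levels are TMM-scaled CPM, counts relative to library size, as mean ± SD with n = 4 per group.

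After Romidepsin, 12 of 17 tested histone genes and 6 of 11 genes better known from neurons rose, while 11 of 36 interferon-stimulated, 11 of 31 neutrophil and 5 of 29 monocyte and macrophage genes fell. With the samples paired by a replicate block, 33, 23 and 21 genes of these 3 lists fell, and without treated replicate 3, 33, 13 and 16. As lists, none of these passed when the correlation between genes was estimated. Only 11 of the 37 listed neuronal genes had enough counts to be tested. Over all 12852 tested genes, 2610 rose and 2080 fell, while 2667 fell with the block and 3010 without treated replicate 3. The unpaired monocyte count lies near the share of all genes that fell. In the highest of 5 equal classes of expression in untreated replicates 1 and 2, 28.9% fell, near the unpaired interferon share. In the lowest class, 29.6% of genes rose. The linker histone gene Hist1h1c rose from 36.6 ± 10.6 to 1716 ± 458 CPM (log2 fold change 5.55 ± 0.34, adjusted p = 2.14e-04), and H1f0, the replacement linker histone gene, rose from 129 ± 22.8 to 1451 ± 551 CPM. Ptgs2, which encodes the prostaglandin-producing enzyme COX-2, rose from 3.22 ± 0.785 to 143 ± 138 CPM (log2 fold change 5.46 ± 0.94, adjusted p = 0.00387). Treated replicates 1 to 4 held 272, 251, 18.2 and 28.7 CPM of Ptgs2. In the other direction, Ciita, the master regulator of MHC class II genes, fell from 56.4 ± 32.8 to 2.20 ± 0.766 CPM (log2 fold change −4.68 ± 0.47, adjusted p = 6.72e-04). Mcl1, which encodes a pro-survival BCL2 family protein, fell from 1778 ± 330.0 to 611 ± 382 CPM. On GRCm38, these genes are annotated at chromosome 13, 23738808 to 23740367 (Hist1h1c), chromosome 15, 79028450 to 79030504 (H1f0), chromosome 1, 150100031 to 150108227 (Ptgs2), chromosome 16, 10480059 to 10528418 (Ciita) and chromosome 3, 95658788 to 95663176 (Mcl1).

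In edgeR's unpaired quasi-likelihood test with Benjamini-Hochberg adjustment, 2610 of 12852 tested genes were higher and 2080 lower in treated cells. Together these are 36.5% of the genes tested. With the samples paired by the replicate block, 2719 were higher and 2667 lower. At least 2-fold differences were found for 1611 of the higher and 1325 of the lower genes. All treated libraries lay on one side of all untreated ones for 4524 genes (35.2%), against 2.86% if all libraries were interchangeable. The balance of the directions depended on the scaling. Higher genes made up 55.7% of the calls with TMM scaling, 74.0% with library size alone (3886 higher, 1368 lower) and 87.6% with scaling to 20 housekeeping genes (5386 higher, 764 lower), which moved the fold change of all genes by 0.30 and 0.69, respectively. Fold changes below are therefore relative to the TMM scale. Housekeeping scaling used the summed counts of the 20 genes, so abundant ones weigh most. Actb, at 6517 CPM in untreated cells, itself fell, while Emc7 was at 79.6 CPM. Housekeeping scaling ended the calls of 25 of the lower genes examined singly, among them Trem2, Bcl2l1, Cd274, Cdkn1b, Axl, Insig1, Herpud1, Mki67, Rrm2, Pfkl, Rela, Nfkb1, Ywhaz and Actb.

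Among libraries, the correlation of log2 CPM was 0.945 to 0.974 within the untreated group and 0.880 to 0.966 within the treated group. Treated replicate 3 correlated better with untreated libraries (mean r = 0.934) than with the other treated libraries (mean r = 0.910), although its highest single correlation was with treated replicate 4 (0.963, against 0.889 and 0.880 with treated replicates 1 and 2 and 0.925 to 0.946 with untreated libraries). The first principal component held 68.0% of the variance. Treated replicate 3 lay on it at −1.17, between the untreated libraries (−77.3 to −50.6) and the other treated ones (50.3 to 105.0). Those were not alike: treated replicate 4 lay at 50.3, and treated replicates 1 and 2 at 105.0 and 104.1. Mean r with untreated libraries was 0.887 for treated replicate 4, against 0.803 and 0.801 for treated replicates 1 and 2. Without treated replicate 3, 3146 genes were higher and 3010 lower, and with both libraries of number 3 left out, a setting chosen after seeing the data, 2585 were higher and 2434 lower. Leaving out untreated replicate 3 gave 1716 higher and 1234 lower genes. The number of lower genes was 1216, 1298 and 1183 without treated replicates 1, 2 and 4.

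**Figure D1:**
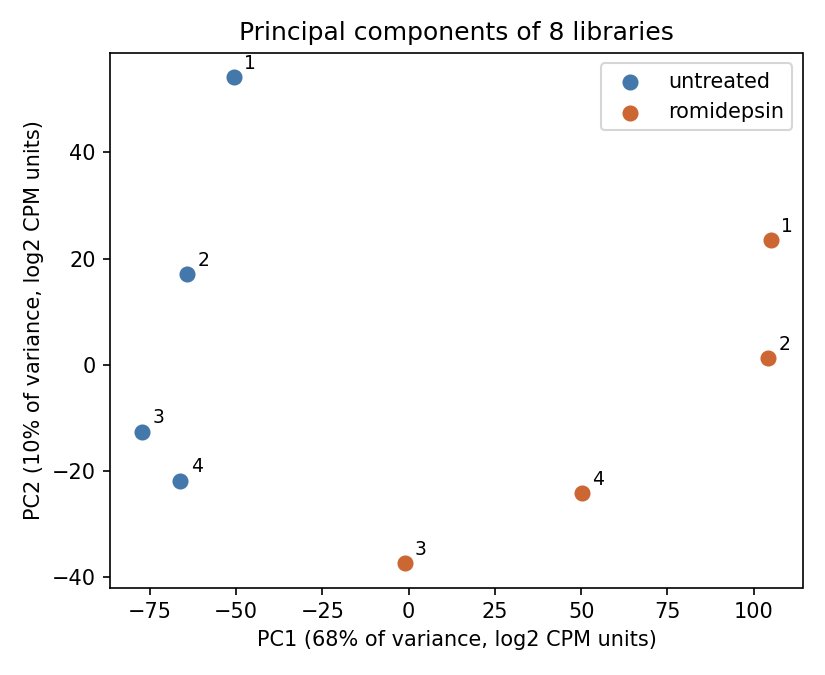
Position of the 8 libraries on the first (68.0% of variance) and second (10.5%) principal components of log2 CPM, coloured by group and numbered by replicate. Treated replicate 3 lies at −1.17 on the first component, between the untreated libraries and treated replicates 1, 2 and 4. Treated replicate 4, at 50.3, lies between it and treated replicates 1 and 2.

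The highest fold changes among genes with a mean of at least 10 CPM and no overlap between groups included 9 genes described here, 8 of which had at most 3.22 CPM in untreated cells, the other being Hist1h1c. Hist1h1d, another linker histone gene, rose from 0.340 ± 0.177 to 53.5 ± 25.1 CPM (log2 fold change 7.24 ± 0.51, adjusted p = 2.36e-04). Dact3, an antagonist of Wnt signalling, rose from 0.482 ± 0.234 to 50.8 ± 22.6 CPM (6.71 ± 0.53, adjusted p = 3.71e-04), and the LIM-domain gene Crip2 by 6.42 ± 0.96 (7.53 without untreated replicate 2). H1fx, a further linker histone gene that overlaps other annotated genes, rose by 5.82 ± 0.76 and the profilin gene Pfn2 by 5.42 ± 0.52. Epb41l5 and Fgfrl1 rose by 4.63 ± 0.42 and 4.54 ± 0.41.

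The lowest fold changes were chosen in the same way. Asgr2, a subunit of the asialoglycoprotein receptor, fell from 31.7 ± 40.2 to 0.730 ± 0.292 CPM (log2 fold change −5.41 ± 0.91, adjusted p = 0.00347), with untreated replicate 1 at 91.9 CPM and the other untreated libraries at 7.98 to 14.5. Without that library its log2 fold change was −3.97. Ccnd1, encoding cyclin D1, had the same profile, at 200.4 CPM in untreated replicate 1 against 10.9 to 29.2 in the others (log2 fold change −3.54 ± 0.90, adjusted p = 0.0165), and without that library its log2 fold change was −1.83 (adjusted p = 0.0145). The membrane-bound protease gene Mmp25 fell from 24.8 ± 8.12 to 1.45 ± 1.30 CPM, the lymphotoxin gene Ltb from 23.2 ± 12.1 to 1.45 ± 0.595 CPM and the immunoglobulin heavy chain gene Ighd from 19.6 ± 11.5 to 1.57 ± 0.493 CPM. Further genes of this set were Asprv1 (−3.83 ± 0.72), Il1f9 (−3.56 ± 0.75), the endosomal RNA sensor Tlr7 (−3.36 ± 0.97) and Dis3l (−3.36 ± 0.49). Without treated replicate 3, Tlr7 was at −4.74, Dis3l at −4.14 and Il1f9 at −4.23, and Asprv1 was at −4.67 without treated replicate 4 and Mmp25 at −4.90 without treated replicate 2. The calls of Tlr7 (adjusted p = 0.119) and Ccnd1 (adjusted p = 0.0831) were lost when no count filter was applied, that of Ccnd1 also with limma-voom (0.0618) and that of Tlr7 also without untreated replicate 3 or 4 or treated replicate 4 (adjusted p up to 0.0674).

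**Figure D2:**
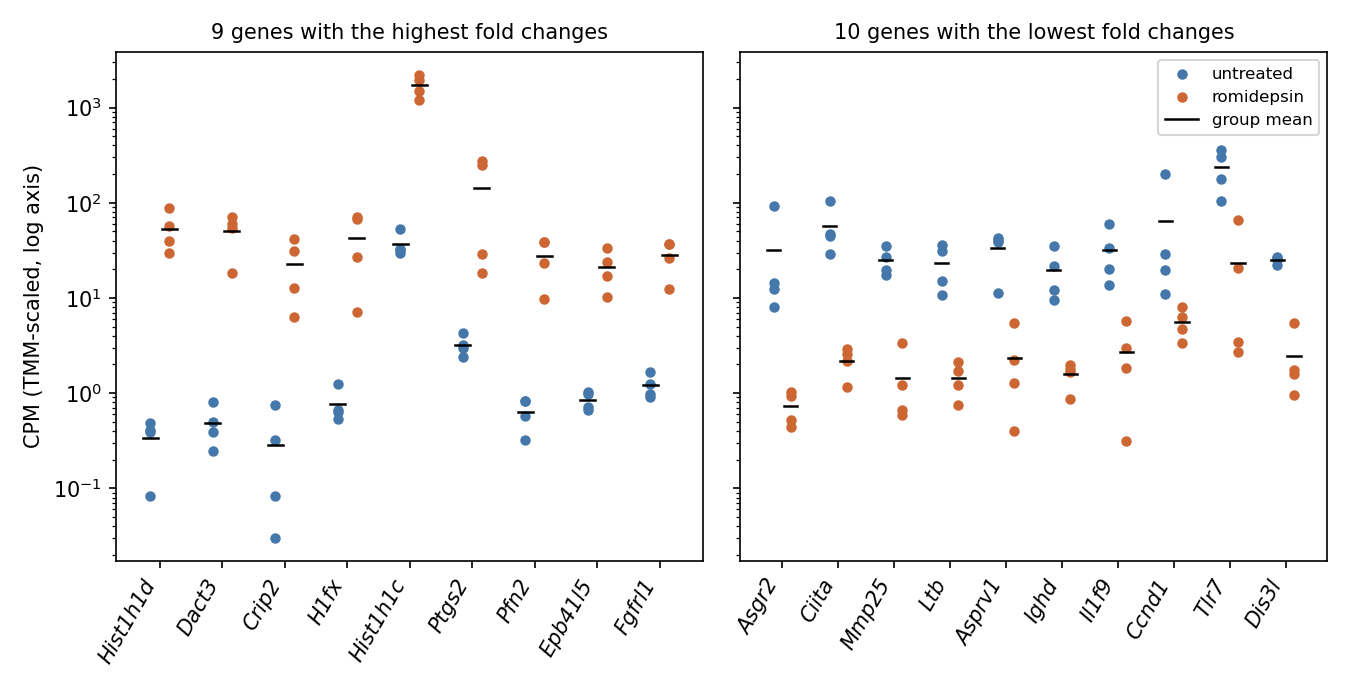
TMM-scaled CPM of 9 genes with the highest and the 10 with the lowest fold changes, on a log axis. Points are the 4 libraries of a group, bars are group means, and a count of 0 is drawn at 0.03 CPM; Hist1h1c is the most abundant of the higher genes after treatment, at 1716 ± 458 CPM (mean ± SD).

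For 29 gene lists fixed before the data were examined, members were counted by their own tests and each list was compared with all other genes by camera. With a preset correlation between genes, 13 lists passed, 2 higher and 11 lower. No list passed with an estimated correlation (1 had an unadjusted p under 0.05), and 15 of the 35 ways of splitting the 8 libraries into 4 and 4, the real one included, gave at least 13 such calls. Of the 13, the histone and neuronal lists were the only ones whose p was smaller in the real split than in any other. All splits used the same filtered genes. For the neuronal list that filter favours rises in treated cells, as described below, so this comparison does not set that list apart. By contrast, no other split called more than 1 gene, so members are described below by their counts. These counts are to be read against all 12852 tested genes, of which 2610 rose and 2080 fell. In the highest of 5 equal classes of expression in untreated replicates 1 and 2, 28.9% of genes fell, and in the lowest 29.6% rose. A count near these shares does not set a list apart from other genes. Some genes stand in more than 1 list. Where no member of a list rose or fell by this count, DESeq2 called no member in that direction either and none had an unadjusted p under 0.05 in edgeR, except 2 higher lipid-handling genes (1 in DESeq2) and 1 lower erythroid gene.

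Of 17 tested histone genes, 12 rose, none fell and 5 did not pass (13 rose when adjusted over the list alone, and 1 fell without treated replicate 3; camera adjusted p = 6.16e-08, adjusted p = 0.543 with an estimated correlation). The core histone gene Hist1h4i rose from 2.0 ± 0.358 to 11.6 ± 3.24 CPM, beside Hist1h1c and H1f0. Histone cluster genes resemble each other closely, so reads may have been split between copies and single values are uncertain. The poly(A) selection also means that only polyadenylated histone transcripts were measured. Of 37 neuronal genes, 35 were in the count table and only 11 passed the count filter. A gene nearly absent from untreated cells passes that filter only if treated cells express it. This favours rises, both in the counts and in the list's test. Of the 11 tested neuronal genes, 6 rose, none fell and 5 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1.94e-04, adjusted p = 0.543 with an estimated correlation). The synapsin gene Syn1 rose from 12 ± 2.16 to 55.4 ± 5.15 CPM (log2 fold change 2.21 ± 0.18, adjusted p = 3.71e-04), although it shares its locus with Araf on the other strand. The tubulin gene Tubb2b rose by 4.03 ± 0.38 and the ubiquitin hydrolase gene Uchl1 by 2.59 ± 0.41.

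Of 36 tested interferon-stimulated genes, 11 fell and 25 did not pass, with 11 when adjusted over the list alone, whereas 33 fell with the replicate block, 33 without treated replicate 3 and 25 without both libraries of number 3. None rose in any of these fits. Irf9, a subunit of the interferon-activated ISGF3 complex, fell from 147 ± 13.4 to 40.4 ± 22.9 CPM (log2 fold change −1.86 ± 0.33, adjusted p = 0.00435), although it overlaps Rnf31 on the same strand and its value is uncertain, and the RNA-sensing helicase homologue Dhx58 (−1.89 ± 0.47). Treated replicate 3 held 74.4 CPM of Irf9 and the other treated libraries 26.5 to 33.8. The list's camera adjusted p was 4.13e-06, and adjusted p = 0.550 with an estimated correlation.

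Among 31 neutrophil granule and maturation genes, 11 fell, none rose and 20 did not pass (15 fell when adjusted over the list alone; 23 with the replicate block). Cebpe and Gfi1, transcription factors of granulocyte development, fell (−3.13 ± 0.49 and −2.94 ± 0.55), as did Mmp25. The alarmin genes S100a8 (−1.54 ± 0.69, adjusted p = 0.106) and S100a9 (−1.43 ± 0.72, adjusted p = 0.144) did not pass and were higher in 1 of 4 pairs; DESeq2 called S100a8 (adjusted p = 0.0320). The list's camera adjusted p was 4.78e-08, and adjusted p = 0.543 with an estimated correlation. Among 29 monocyte and macrophage genes, 5 fell and 24 did not pass (none when adjusted over the list alone), against 21 lower with the replicate block, 16 without treated replicate 3 and 10 without both libraries of number 3. Spi1, the myeloid master regulator PU.1, fell from 539 ± 94.6 to 91.2 ± 94.9 CPM (log2 fold change −2.56 ± 0.69, adjusted p = 0.0204), a call lost without treated replicate 4 (adjusted p = 0.0546) or with no count filter (0.0892). Its log2 fold change was −3.55 without treated replicate 3, which held 225.4 CPM against 20.5 to 90.8 in the other treated libraries. The lysozyme gene Lyz2 (−0.74 ± 0.33, adjusted p = 0.105) passed only with the block (adjusted p = 0.0199) and in DESeq2 (0.0149). Camera gave adjusted p = 2.93e-04 for this list, and adjusted p = 0.550 with an estimated correlation.

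Of 37 tested myeloid transcription factors, 16 fell, 2 rose and 19 did not pass (22 and 3 when adjusted over the list alone; 22 lower and 4 higher with the replicate block, 23 and 4 without treated replicate 3, 8 and 4 with housekeeping scaling). Bhlhe40 fell (−1.53 ± 0.26), while the immediate early gene Nr4a1 rose from 5.83 ± 1.51 to 108 ± 121 CPM (log2 fold change 4.21 ± 0.73, adjusted p = 0.00390), with treated replicate 2 at 287.7 CPM and the other treated libraries at 28.5 to 62.5. Without treated replicate 2 its log2 fold change was 3.05. Camera gave adjusted p = 3.25e-04, and adjusted p = 0.543 with an estimated correlation. Of 24 chemoattractant receptors and adhesion molecules, 7 fell, none rose and 17 did not pass (4 when adjusted over the list alone; 16 with the replicate block, 16 without treated replicate 3 and 15 without both libraries of number 3). With housekeeping scaling 6 fell and 1 rose. The adhesion molecule gene Pecam1 fell (−1.64 ± 0.31). Cxcr2, the neutrophil chemokine receptor, fell from 42.4 ± 20.7 to 7.86 ± 5.57 CPM, a call lost with no count filter (adjusted p = 0.0657), and the complement receptor C3ar1 (−2.60 ± 1.14, adjusted p = 0.101) passed with the block (adjusted p = 0.00875), without treated replicate 3 (0.00951) and with limma-voom (0.0409). The list's camera adjusted p was 8.49e-05, and adjusted p = 0.543 with an estimated correlation.

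Of 26 lipid-handling myeloid genes, a list built around Apoe and Trem2, 8 fell, none rose and 18 did not pass (8 when adjusted over the list alone). With the replicate block 16 fell and 2 rose, and without treated replicate 3, 13 fell. With library size 5 fell and 2 rose, and with housekeeping scaling 3 fell and 2 rose. Trem2, a lipid-sensing receptor of macrophages, fell from 105 ± 24.3 to 44.4 ± 29.1 CPM (log2 fold change −1.24 ± 0.42, adjusted p = 0.0443), but the call was lost when any one of the libraries other than treated replicate 3 was left out (adjusted p 0.0576 to 0.108), with library size scaling (0.0509) and with no count filter (0.107). Apoe, the apolipoprotein E gene (chromosome 7, 19696109 to 19699188, GRCm38), was at 13608 ± 7746 CPM in untreated and 7647 ± 4745 CPM in treated cells. Its fold change did not pass (−0.83 ± 0.71, adjusted p = 0.371), although it was lower in all 4 pairs and passed with the replicate block (−1.02, adjusted p = 0.0289). The receptor kinase gene Axl fell (−1.17 ± 0.31), a call lost without treated replicate 2 (adjusted p = 0.0512). Camera gave adjusted p = 0.00318 for the list, and adjusted p = 0.550 with an estimated correlation.

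Among 25 myeloid suppressor effectors, 10 fell, 3 rose and 12 did not pass (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0388, adjusted p = 0.543 with an estimated correlation). The list lost its call without untreated replicate 4 (adjusted p = 0.0751) or treated replicate 2 (0.0546), and with housekeeping scaling 5 members fell and 4 rose. The NADPH oxidase subunit gene Ncf1 fell from 823 ± 96.3 to 107 ± 111 CPM (log2 fold change −2.95 ± 0.66, adjusted p = 0.0106, or −3.98 without treated replicate 3, which held 268.7 CPM against 24.9 to 86.7) and the cystine transporter gene Slc7a11 from 33.8 ± 17.4 to 9.56 ± 4.43 CPM, while Ptgs2 rose. Slc7a11 was no longer called with housekeeping scaling (adjusted p = 0.0927). Arg1, the arginine-degrading arginase, was at 261 ± 237 CPM in untreated and 32.2 ± 42.9 CPM in treated cells. It did not pass (−3.02 ± 1.25, adjusted p = 0.0835) but was lower in all 4 pairs and passed with the replicate block (adjusted p = 0.00331), without treated replicate 3 (0.0179), without both libraries of number 3 (0.0359) and in DESeq2 (0.0384). Cd274, the gene of the checkpoint ligand PD-L1, fell from 153 ± 55.9 to 69.8 ± 36.9 CPM (−1.13 ± 0.38, adjusted p = 0.0445), with treated replicate 3 at 125.1 CPM and the other treated libraries at 48.9 to 53.1. That call was lost without untreated replicate 2, 3 or 4 or treated replicate 1, 2 or 4 (adjusted p up to 0.113), with library size scaling (0.0595) and with no count filter (0.0686). The nitric oxide synthase gene Nos2 did not pass (−0.16 ± 0.61, adjusted p = 0.846), and its sign turned with library size (0.19) or housekeeping scaling (0.67), without both libraries of number 3 (0.20), and without untreated replicate 3 (0.05) or treated replicate 4 (0.19).

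Of 23 tested dendritic cell and MHC class II genes, 5 fell, none rose and 18 did not pass (1 when adjusted over the list alone). With housekeeping scaling 1 fell and 3 rose, with library size 3 fell and 1 rose, and without treated replicate 3, 7 fell and 1 rose. With the replicate block 9 fell and 2 rose (camera adjusted p = 0.00613, adjusted p = 0.543 with an estimated correlation). Beside Ciita, the MHC class II invariant chain gene Cd74 was at 2246 ± 1086 CPM in untreated and 1234 ± 430.3 CPM in treated cells, and passed with the block alone (adjusted p = 0.0278). Of 12 B and plasma cell markers, 7 fell, none rose and 5 did not pass (8 when adjusted over the list alone; 3 without both libraries of number 3 and 3 with housekeeping scaling; camera adjusted p = 9.29e-04, adjusted p = 0.543 with an estimated correlation). Cd79b fell from 40.4 ± 25.1 to 4.72 ± 2.30 CPM, Cd22 from 31.3 ± 11.7 to 6.85 ± 1.75 CPM and Blk from 6.61 ± 4.24 to 0.783 ± 0.552 CPM, and Ighm, at 331 ± 215 CPM in untreated cells, passed with the block (adjusted p = 0.0188) and without treated replicate 2 (0.0273). Of 11 mast cell, basophil and eosinophil markers, 4 fell and none rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00613, adjusted p = 0.543 with an estimated correlation). Il5ra fell from 2.25 ± 1.94 to 0.240 ± 0.144 CPM and Cd200r3 from 3.48 ± 1.37 to 0.498 ± 0.378 CPM. The B cell and mast cell lists hold markers of cells other than MDSCs. The mast cell list lost its call without treated replicate 3 (adjusted p = 0.0505) and with a minimum mean of 10 CPM (0.342), and the MHC class II list without treated replicate 3 (0.0515). Of 7 T and NK cell markers, Cd3d alone fell (−1.98 ± 0.67, adjusted p = 0.0446; none when adjusted over the list alone), a call lost with the replicate block (adjusted p = 0.0695), with limma-voom (0.0868), with library size scaling (0.0673), with housekeeping scaling, and without untreated replicate 1 or 2 or treated replicate 1, 2 or 3 (up to 0.113). With the block, and also without treated replicate 3, 1 T and NK cell marker other than Cd3d was lower. Of 6 erythroid and megakaryocyte markers, Epor alone rose (2.31 ± 0.64, adjusted p = 0.0221), a call lost without untreated replicate 3 or treated replicate 1 or 4 (adjusted p up to 0.0603), and 2 rose without treated replicate 3, without both libraries of number 3 and with housekeeping scaling. None of 9 epithelial, stromal and endothelial markers passed, but 1 was higher with the replicate block. Camera gave adjusted p = 0.332, 0.916 and 0.857 for the T and NK cell, erythroid and epithelial lists.

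Genes that govern cell death were tested as a pro-survival and a pro-apoptotic list. Of 12 tested pro-survival BCL2 family and IAP genes, 5 fell, none rose and 7 did not pass, with 5 when adjusted over the list alone and 8 with the replicate block (9 without treated replicate 3, 8 without both libraries of number 3, 4 lower and 1 higher with housekeeping scaling; camera adjusted p = 0.00509, adjusted p = 0.543 with an estimated correlation). Xiap, an inhibitor of caspases, fell from 93.7 ± 17 to 32.4 ± 12 CPM (log2 fold change −1.53 ± 0.26, adjusted p = 0.00360), the caspase-8 regulator gene Cflar (−1.72 ± 0.37) and Birc3 (−1.46 ± 0.32). Mcl1 (−1.54 ± 0.42, adjusted p = 0.0201) lost its call without untreated replicate 3 or treated replicate 1 or 4 (adjusted p up to 0.0547). Bcl2l1, encoding BCL-XL, fell (−1.02 ± 0.30), a call lost without untreated replicate 1 or 3 or treated replicate 1, 2 or 4 (adjusted p up to 0.0717) and with library size scaling (0.0675). Of 20 pro-apoptotic genes, 3 rose and 4 fell, also when adjusted over the list alone, and the list test did not pass (adjusted p = 0.776, with a median of 0.11 but a mean of −0.12). These pro-apoptotic counts lie near the shares of all tested genes that rose and fell. The block gave 3 higher and 6 lower, leaving out treated replicate 3 gave 4 and 7, library size 7 and 3, and housekeeping scaling 10 and 4. Bik rose by 2.76 ± 0.45, and the mitochondrial pore gene Bak1 and the TNF receptor gene Tnfrsf1a fell (−2.01 ± 0.42 and −1.27 ± 0.24).

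Senescence-related lists did not pass as lists. Of 34 secretory phenotype genes, 7 rose, 4 fell and 23 did not pass (the same when adjusted over the list alone; 9 and 8 with the replicate block, 7 and 7 without treated replicate 3; camera adjusted p = 0.635). The list's median was −0.31, positive with housekeeping scaling (0.31), and its mean 0.05. The chemokine gene Cxcl1 rose from 5.85 ± 2.14 to 43.5 ± 33.0 CPM, the collagenase gene Mmp13 from 37.3 ± 13.9 to 141 ± 25.7 CPM and the interleukin genes Il1a and Il1b by 2.19 ± 0.44 and 2.65 ± 0.64, whereas Mmp14 fell from 294 ± 91.2 to 35.0 ± 31.8 CPM. Treated replicate 3 held 33.1 CPM of Il1b, within the untreated range of 24.3 to 34.8, and the other treated libraries 76.8 to 343 CPM. With no count filter, Il1b (adjusted p = 0.0656) and Mmp14 (0.0541) were no longer called. Il6 had 6 to 22 counts per untreated and 2 to 14 per treated library and was too rare to test. Of 7 CDK inhibitor genes, Cdkn2b rose from 0.597 ± 0.165 to 4.45 ± 3.63 CPM and Cdkn1b fell from 109.6 ± 6.08 to 52.6 ± 29.9 CPM, the latter called only at adjusted p = 0.0451 and not over the list alone. With library size 3 of the 7 rose and none fell, and with housekeeping scaling 6 rose and none fell. Without any one of the libraries other than treated replicate 3, the Cdkn1b call was lost (adjusted p up to 0.107), as it was with library size scaling (0.0598) or no count filter (0.0668). Cdkn1a, encoding p21, did not pass (0.26 ± 0.18, adjusted p = 0.268). It passed with library size (0.0363) and housekeeping scaling (0.01). Cdkn2a was too rare to test, with 2 to 10 counts per untreated library and 64, 24, 5 and 2 counts in treated replicates 1 to 4. Of 20 p53 target genes, 4 rose and 1 fell, also over the list alone (camera adjusted p = 0.327). Without treated replicate 3, 5 rose and 2 fell, and 7 rose with library size and 10 with housekeeping scaling, where none fell. Gadd45a rose by 1.62 ± 0.16 and the death receptor gene Tnfrsf10b by 2.89 ± 0.26.

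Among the HDAC genes themselves, 3 of 11 rose and 1 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.547). With the replicate block 3 rose and 2 fell, without treated replicate 3, 4 rose and 2 fell, without both libraries of number 3, 3 rose and 2 fell, and with housekeeping scaling 6 rose and 1 fell. Hdac1 rose from 60.7 ± 5.23 to 118 ± 25.6 CPM, Hdac3 from 52.9 ± 6.37 to 100.5 ± 23.9 CPM and Hdac6 from 18.3 ± 1.96 to 36.5 ± 6.53 CPM, and Hdac7 fell from 33.4 ± 1.05 to 11.1 ± 6.94 CPM. Hdac2 did not pass (0.50 ± 0.19, adjusted p = 0.0632), but did without untreated replicate 1 (0.0456), without treated replicate 3 (0.0275) and with library size (0.0230) or housekeeping scaling (0.00762). Of 24 heat shock and stress response genes, 9 rose and 3 fell (10 and 3 when adjusted over the list alone; 14 and 2 with library size, 16 and 0 with housekeeping scaling; camera adjusted p = 0.0703). Hspa1a and Hspa1b, near-identical copies whose separate values are uncertain, rose by 3.17 ± 0.49 and 3.81 ± 0.53, and Herpud1 fell (−1.16 ± 0.22). Of 24 homologous recombination and checkpoint genes, 7 rose and 1 fell, also over the list alone (camera adjusted p = 0.339), against 11 higher without treated replicate 3 and 13 with housekeeping scaling, with Blm higher by 1.48 ± 0.32 and Nbn lower (−1.70 ± 0.29). Of 34 cell cycle genes, 2 rose and 6 fell (1 and 4 over the list alone; camera adjusted p = 0.409). With library size 2 rose and 3 fell, and with housekeeping scaling 8 rose and none fell. The list's median of −0.05 turned to 0.03 with upper-quartile, 0.26 with library size and 0.68 with housekeeping scaling. Mki67 fell from 184 ± 61.3 to 75.4 ± 19.1 CPM and Rrm2 (−1.39 ± 0.26), and Pcna rose by 0.77 ± 0.20. Of 27 NF-kB target genes, 2 rose and 6 fell, also over the list alone, and 10 fell with the replicate block, 11 without treated replicate 3 and 10 without both libraries of number 3 (camera adjusted p = 0.0703). With library size 2 rose and 3 fell. With housekeeping scaling 5 rose and 2 fell, and the median of −0.37 turned to 0.27. Rela and Nfkb1 fell (−0.74 ± 0.13 and −0.82 ± 0.21), the latter not called with library size scaling (adjusted p = 0.0868), and Nfkbiz rose by 1.80 ± 0.32.

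For metabolism, 5 of 20 cholesterol synthesis genes rose and 2 fell (camera adjusted p = 0.307), and 3 of 22 glycolysis genes rose and 1 fell (camera adjusted p = 0.547), both with the same counts over the list alone. With housekeeping scaling 11 cholesterol synthesis genes rose (8 with library size) and 6 glycolysis genes, and no gene of either list fell. The sterol reductase gene Dhcr7 rose from 26.9 ± 3.56 to 76.2 ± 23.6 CPM, and Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, fell from 40.1 ± 7.49 to 17.5 ± 3.42 CPM. Eno2, the neuronal enolase, rose from 4.11 ± 1.58 to 38.4 ± 4.92 CPM (log2 fold change 3.22 ± 0.28, adjusted p = 5.26e-04), and Pfkl fell (−0.94 ± 0.17) while Pfkm rose by 1.04 ± 0.15. With the replicate block 3 glycolysis genes rose and 3 fell, without treated replicate 3, 3 rose and 5 fell, and without both libraries of number 3, 2 rose and 4 fell. The median of this list, −0.41, turned to 0.25 with housekeeping scaling. Of 20 housekeeping genes, 5 fell and 2 rose, also over the list alone (camera adjusted p = 0.155). Their median of −0.38 turned to 0.30 when their summed counts set the scale (5 higher, none lower). With the replicate block 5 fell and 1 rose. Ywhaz fell (−1.16 ± 0.27) and Actb (−1.14 ± 0.32), the latter called in the full set but not without untreated replicate 2 or 3 or treated replicate 1, 2 or 4 (adjusted p up to 0.0674). None of 7 mitochondrially encoded genes passed (camera adjusted p = 0.571), but 3 were higher with housekeeping scaling. The share of counts from mitochondrially encoded genes was higher in the treated library of all 4 pairs, at 1.89%, 1.82%, 0.934% and 1.58% in untreated and 3.05%, 2.42%, 1.59% and 2.39% in treated replicates 1 to 4.

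Leaving out 1 library moved the fold change of 28 of 108 genes named by more than 1.5 times. Genes named only for the processing settings are not among these 108. Some of them also moved that far, such as Cdh1 and Ifit2, whose ranges are given with those settings. Beside the genes for which this is given above, log2 fold changes without treated replicate 3 were −4.58 for Arg1, −4.39 for C3ar1, −3.76 for Mmp14, −3.67 for Tlr6, −3.57 for Gfi1, −3.55 for Psmb10, −2.62 for Bak1 and −2.48 for Dhx58. Without treated replicate 2 they were −2.82 for Ighm, −2.11 for Ms4a1, −2.07 for Igkc, −1.25 for Jchain and −0.19 for Ebf1. Without treated replicate 4 they were −2.15 for S100a8 and −2.16 for S100a9. Without untreated replicate 2 they were −2.42 for Il5ra, −2.29 for Arg1, 1.14 for Ebf1, 0.69 for Jchain and 0.43 for Igkc, and without untreated replicate 4 the value for Epor was 3.25.

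**Figure D3:**
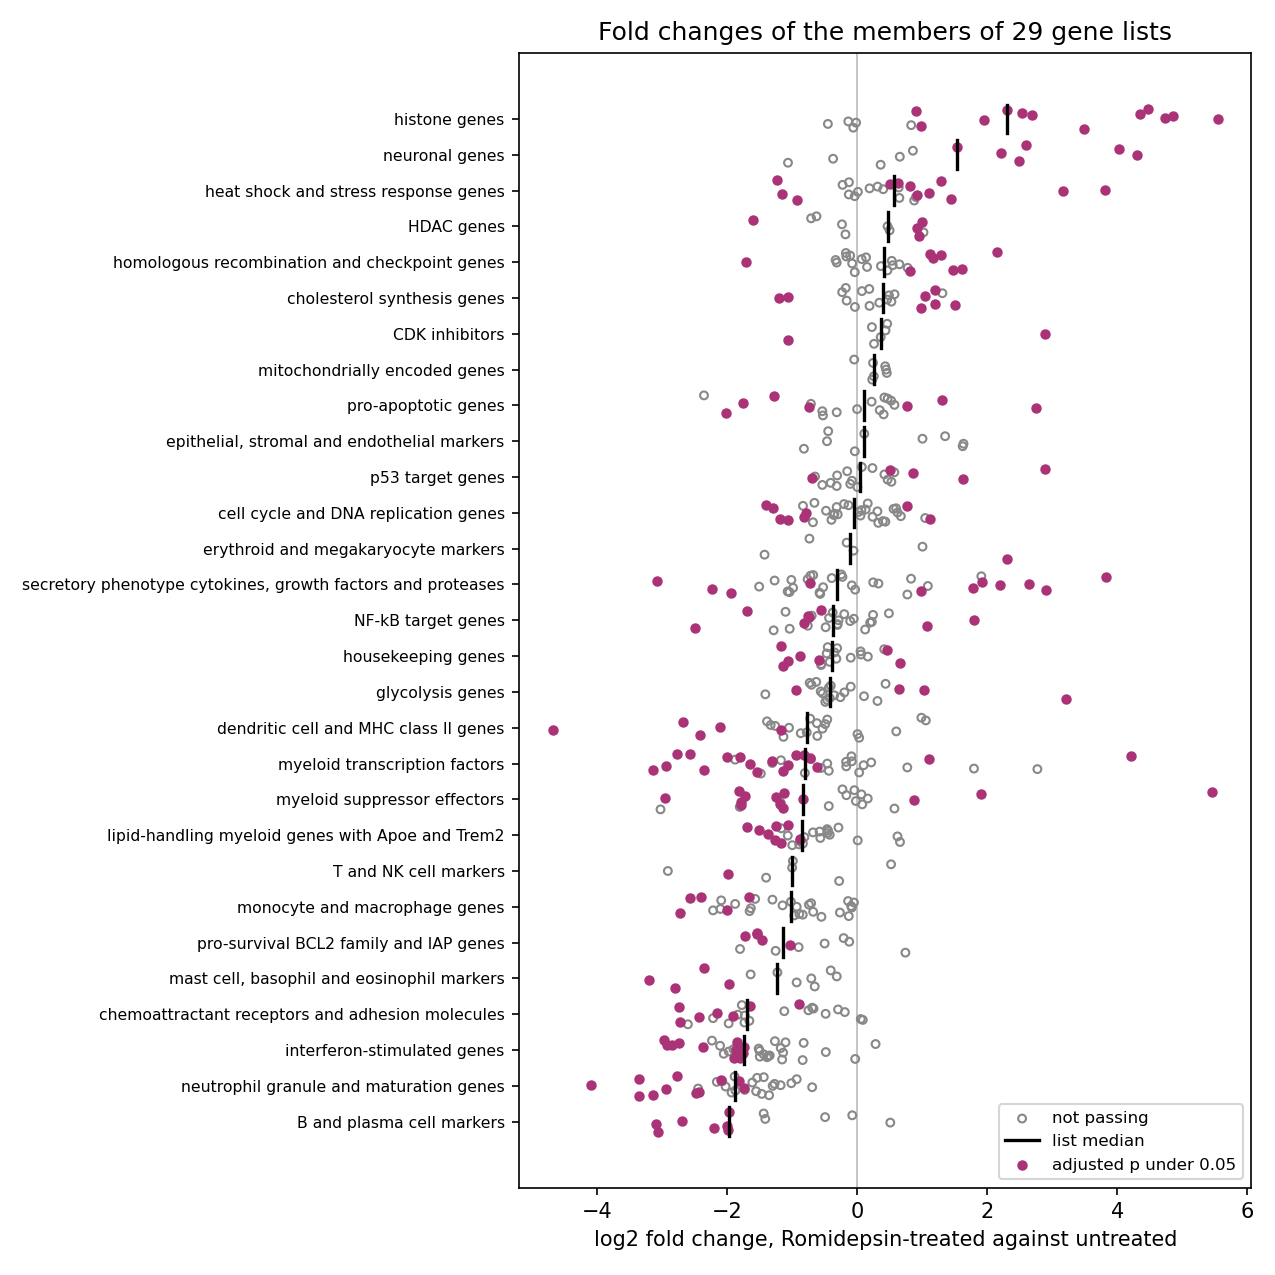
Log2 fold changes of the tested members of the 29 gene lists, ordered by list median. Filled points passed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, open circles did not, and black bars are list medians; 12 of 17 histone genes lie to the right as filled points, and none of the 11 called interferon-stimulated genes does.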

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

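All tests on treated replicate 3 were chosen after its position was seen. Results were singled out here where 1 of the 4 libraries of a group stood far from the others, measured as its gap to the nearest library divided by the range of the group. Chance alone gives about 1 in 20 groups, and 19 of 220 groups examined were singled out. Untreated replicate 4 held 23176949 counts against 12996892 to 14542692 in the other untreated libraries (ratio 0.848). Untreated replicate 1 stood apart for Asgr2 (91.9 CPM against 7.98 to 14.5, ratio 0.923), Ccnd1 (200.4 against 10.9 to 29.2, 0.903), Bik (1.84 against 0.578 to 0.677, 0.922), Hdac1 (68.5 against 57.7 to 58.4, 0.934), Nfkbiz (55.2 against 42.5 to 42.7, 0.981) and Rps10 (5.28 against 2.71 to 2.97, 0.896). Untreated replicate 2 did so for Hist1h1c (52.4 against 29.6 to 32.7 CPM, 0.864) and Tnfrsf10b (1.90 against 2.71 to 2.85, 0.853), untreated replicate 3 for Asprv1 (11.2 against 39.0 to 42.1, 0.900) and Bak1 (189.5 against 155.6 to 158.2, 0.924), and untreated replicate 4 for Tubb2b (1.16 against 0.480 to 0.575, 0.859). Treated replicate 2 stood apart for Nfkb1 (102.6 against 74.3 to 78.9 CPM, 0.839) and Nr4a1 (287.7 against 28.5 to 62.5, 0.869), and treated replicate 4 for Cd3d (1.23 against 0.401 to 0.463, 0.925). Treated replicate 3 did so for 4 genes that fell, Cd274 (125.1 against 48.9 to 53.1 CPM, 0.945), Gfi1 (2.65 against 0.746 to 0.906, 0.916), Irf9 (74.4 against 26.5 to 33.8, 0.848) and Pecam1 (13.9 against 6.80 to 7.23, 0.939).

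Treated replicate 3 lay closer to the untreated libraries than the other treated libraries did. Lower depth is argued against, as its total was 1.051 times the highest of the other treated libraries, and so is an untreated library under a treated label, since 89.7% of 184 genes at least 4-fold higher in pair 1 exceeded all untreated libraries in it, against 9.78% to 41.8% when each untreated library was set against the other 3. A mixture of treated and untreated material and a weaker or later response cannot be told apart: the implied treated share was 0.334 from rising and 0.541 from falling genes, a gap of 0.207 (95% bootstrap interval over genes, which are not independent, 0.151 to 0.240). The gap lies above the bound of 0.1 that was set first and above those of simulated mixtures, run last (0.0937 at a share of 0.4, 0.131 at 0.7), but pair 4, compared after the first result, had a gap of 0.225, so a gap of this size is not particular to this library and does not decide. No biological explanation was tested, since the labels name no difference between replicates.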

How the results depend on the processing

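Leaving out both libraries of number 3, the estimated correlation with the replicate block, and the comparison of single lists between splits were chosen after seeing the data. The counts of higher and lower genes stayed within 1.5 times with DESeq2 size factors, upper-quartile scaling, no count filter, the DESeq2 Wald test, limma-voom and the replicate block (2719 higher, 2667 lower), and genes shared with the reported calls had the same direction in every setting tried (3348 to 4676 shared in the settings that kept all libraries, 2936 to 4594 with libraries left out). They moved with library size alone (1368 lower, 2559 at least 2-fold higher), housekeeping scaling (5386 higher, 764 lower, 4356 and 587 at least 2-fold) and a mean CPM of at least 10, where fewer genes were tested (889 at least 2-fold higher). Without 1 library, higher genes ranged from 1716 (untreated replicate 3) to 3146 (treated replicate 3), lower genes from 1183 (treated replicate 4) to 3010 (treated replicate 3), and at least 2-fold lower genes from 853 (treated replicate 1) to 2159 (treated replicate 3); for why these moved, the cause was not tested. In simulated data of this comparison (12852 genes, 200 of them changed), edgeR recovered 96% of genes changed 8-fold and 4% of those changed 2-fold, with 2.27% false calls, and DESeq2 made 22.5% false calls. These shares of false calls do not carry over to the larger number of genes called here.

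The number of lists called stayed at 11 to 16 except with an estimated correlation, where 0 passed, also with the replicate block (0). The block leaves few degrees of freedom among the 8 libraries for that test, so the 0 with the block adds little. Fry did not call the lipid-handling (adjusted p = 0.0554), monocyte (0.0720), interferon (0.0797) and B cell (0.0554) lists, and called the p53, NF-kB, heat shock and housekeeping lists. Without untreated replicate 1 the NF-kB (0.0314), heat shock (0.0286) and cholesterol (0.0153) lists passed as well, the NF-kB list also without treated replicate 2 (0.0438), and the heat shock list also without both libraries of number 3 (0.0421) and with a mean CPM of at least 10 (0.0474). The replicate block changed no list call with the preset correlation, and among 154 genes examined singly it ended the call of Cd3d, added 9 (Apoe, Arg1, C3ar1, Cd74, Cybb, Ighm, Lyz2, Mmp8 and Ms4a1) and changed no other call. Of these 154 genes, 19 lost their call with no count filter, 25 with housekeeping scaling and 2 to 23 without 1 library. Signs turned only for genes and lists not called in the reported fit. These were, for library size alone, Birc2 (0.1881), Hdac5 (0.0625), Jchain (0.2917), Nos2 (0.1929), Pf4 (0.1389), Tnfaip2 (0.0998) and Top2a (0.1149) as log2 fold changes, and for housekeeping scaling Aldoa (0.178), B2m (0.0755), Birc2 (0.5809), Ccng1 (0.3005), Cebpb (0.1571), H2afy (0.1924), Hdac5 (0.4263), Ifit2 (0.0631), Igkc (0.3751), Jchain (0.775), Nos2 (0.6746), Pf4 (0.5904), Prss34 (0.2677), Rad50 (0.3537), Tnfaip2 (0.4326) and Top2a (0.5238). Cdh1 turned with limma-voom (1.0518) and the replicate block (1.0097), and ranged from −1.3817 to 2.4132 without 1 library, called only without untreated replicate 1; Nos2 (0.2037) and Jchain (0.3017) turned without both libraries of number 3. With 1 library left out, further turns were in Nos2 (−0.6848 to 0.1869), Pf4 (−0.4383 to 0.0643), Ifit2 (−1.2819 to 0.0981), Tnfaip2 (−0.3089 to 0.0651), Ebf1 (−0.19 to 1.1442), Jchain (−1.2535 to 0.6857) and Igkc (−2.0671 to 0.4334). The adjusted p of lists whose direction turned were 0.9231 (erythroid and megakaryocyte) and 0.8518 (epithelial, stromal and endothelial) with library size, 0.8273 and 0.6644 with housekeeping scaling, and, over the 8 fits without 1 library, 0.07362 to 0.993 (cell cycle, turned in 2), 0.6342 to 0.9911 (erythroid and megakaryocyte, turned in 3) and 0.5768 to 0.9708 (epithelial, stromal and endothelial, turned in 1). DESeq2 gave no adjusted p for 1 of the 154 genes.

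Among the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many called genes (4690, highest other 1) and as many at least 2-fold (2936, highest other 1). Because the numbers pair the samples, the real split is to be compared with those that part all 4 pairs, and the other 7 of these 8 called 0 genes in edgeR, but 8 splits are too few for a share under 0.05. The remaining splits put both libraries of at least 1 number on the same side. For lists, 15 splits gave at least the 13 calls of the real one (highest other 17; 4 of the 8 that part all pairs, highest other 14), so chance cannot be excluded for that number.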

Other observations

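The gene families and the B cell tests below were chosen after the data were seen, the shorter marker set after the values of the single markers, and the untreated control and the other scalings of the baseline test after its first result; the other baseline tests were written before their results were seen. Of 10 gene families read off their symbols, 4 held changes described here. Both tested metallothionein genes, which encode metal-binding stress proteins, rose, Mt2 from 30.1 ± 11.6 to 574 ± 323 CPM (log2 fold change 4.26 ± 0.54, adjusted p = 0.00153) and Mt1 from 97.3 ± 36.7 to 855 ± 508 CPM (3.14 ± 0.54, adjusted p = 0.00384), each in all 4 pairs. Of 10 tested toll-like receptor genes, 7 fell, none rose and 3 did not pass, and 9 fell with the replicate block. Tlr6 fell from 24.9 ± 5.67 to 3.30 ± 2.78 CPM and Tlr9, a B cell and dendritic cell receptor for DNA, from 49.7 ± 35.1 to 10.0 ± 6.36 CPM, the latter no longer called without treated replicate 4 (adjusted p = 0.0506) or with no count filter (0.0800). Of 47 proteasome subunit genes, 8 rose and 4 fell, against 16 and 3 with library size and 31 and 2 with housekeeping scaling. The interferon-inducible subunit genes Psmb8, Psmb9 and Psmb10 fell (−1.22 ± 0.34, −1.26 ± 0.33 and −2.58 ± 0.72), whereas Psmd5 rose by 1.12 ± 0.22. The calls of Psmb9 and Psmb10 were lost without untreated replicate 3 or treated replicate 4, that of Psmb10 with no count filter, and that of Psmb8 without any of 5 libraries and with housekeeping scaling, at adjusted p up to 0.0523, 0.0565 and 0.0627 when 1 library was left out. Of 82 cytosolic ribosomal protein genes, only Rps10 was called (higher, 1.35 ± 0.31, at 3.44 CPM in untreated cells, with reads that near-identical copies can share), and the family median of −0.25 turned to 0.04 with library size and 0.47 with housekeeping scaling (5 higher). Each of the other 6 families, tubulins, potassium channels, Zfp zinc finger genes, C-type lectins, complex I subunits and mitochondrial ribosomal proteins, held genes called in both directions.

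Of 12 B and plasma cell markers, 7 were lower in treated cells and 5 were not called (camera adjusted p = 0.543 with an estimated correlation), with 5 lower with library size and 3 with housekeeping scaling, where the list's median log2 fold change of −1.97 became −1.63 and −1.16. Fewer B cells in the treated cultures would lower every marker by about the same factor, but the mean paired log2 fold changes of 12 markers ranged from −2.91 for Cd79b to 0.41 for Ebf1 (permutation test of differences between markers, p = 1e-05, the smallest it can give). That does not decide, because Ebf1, Jchain, Ighm and Igkc can be expressed by other cells or remain as free transcripts, and among the 8 other markers the difference (−2.91 for Cd79b to −1.52 for Ms4a1, permutation p = 0.009) rested on Cd79b, without which p was 0.21. Fewer B cells, perhaps with a further loss of Cd79b, and lower transcription in the B cells present therefore cannot be told apart. The most abundant markers, Ighm and Igkc, averaged 227.7 and 117.9 CPM over all libraries, and the labels describe no cell sorting.

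Genes that were rare in untreated cells had higher fold changes than abundant ones: in the lowest of 5 equal classes of baseline 29.6% of genes were higher and 5.91% lower, and in the highest 4.67% were higher and 28.9% lower. Whether abundant genes fell depends on the scaling, since the median log2 fold change was 0.47 in the lowest and −0.40 in the highest class with TMM, 0.77 and −0.11 with library size, and 1.15 and 0.26 with housekeeping scaling. Regression to the mean would leave no relation when baseline and fold change come from different libraries, but Spearman's rho across 12852 genes, which are not independent replicates, was −0.301 between baseline in untreated replicates 1 and 2 and fold change in pairs 3 and 4, and −0.295 the other way round. Baseline in untreated replicates 1 and 2 against the difference between untreated replicates 3 and 4 gave 0.0693. Gene length was also argued against, since rho lay at or below −0.236 within each tertile of exon length. The count filter was not tested as a cause. It keeps a gene nearly absent from untreated cells only if treated cells express it. This favours rises in the lowest class, and none of these comparisons can show it. Above that class, at median baselines of 8.98, 25.4, 54.1 and 155 CPM, the relation remained. There the median log2 fold changes in pairs 3 and 4 were 0.16, 0.07, −0.05 and −0.28.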
